A study of Escherichia coli str. K-12 substr. MG1655 with 12 samples.

How the data were processed

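RNA was sequenced from Escherichia coli K-12 cultures that carried either the plasmid pNW129 or the same plasmid with motB, a gene of bacteriophage T4. The cultures were treated with 0.2% arabinose for 20 min at an OD600 of about 0.3 and then received phage T4 at a multiplicity of infection of 10, per the labels' protocols. The 12 libraries form 6 groups of 2 replicates, 1 group for each plasmid at 0, 5 and 10 min after phage addition. Groups and replicate numbers were taken from the sample titles. The strain is given as MG1655 in the sample labels and as TOP10F' in the series' design text. Libraries followed a modified RNATagSeq workflow, per the labels' protocols.

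The values analysed are 5 tables of the authors' own comparisons, 3 for E. coli genes (0, 5 and 10 min) and 2 for T4 genes (5 and 10 min). The authors' tools were STAR 2.5.2, Subread, featureCounts 1.4.6-p3 and DESeq2, per the submitters' processing notes, which are given here without order or role; the columns of the authors' deposited tables are those DESeq2 writes. The genome build, the gene annotation, the handling of reads with several matches and the strand setting are not given in the sources used here. Per the file headers, each deposited table holds for each gene a base mean (a signal in normalised reads, averaged over libraries), a log2 fold change with its standard error, a test score (the Wald statistic), a p-value and an adjusted p-value. The deposited log2 fold change divided by its standard error equalled the deposited score, and the deposited adjusted p-values equalled a Benjamini-Hochberg adjustment over all genes of the table, none missing. The base means were identical in the tables of an organism, so the authors used 1 fit over the time points for each. How many libraries entered that fit, and whether T4 genes were scaled by themselves or with the host, is not given in the sources used here.

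Counts per library were not analysed here. A count model had been planned for that case, and the authors' p-values were taken as they stand instead. Spread between replicates is therefore seen only through the authors' standard errors, how many libraries show a direction cannot be given, and no depth per library can be stated. The base means summed to 9104690 normalised reads for the host, of which 57.2% fell on tRNA genes and 29.8% on protein-coding genes, and to 308038 for T4. The median gene had a base mean of 206 in the host and 497 in T4. The median standard error of a log2 fold change, among host genes with a base mean of at least 10, was 0.33 at 0 min, 0.32 at 5 min and 0.32 at 10 min, and it was 0.15 for T4 genes at both times. The labels do not say that replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

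The headers do not name the numerator of the fold change. The names of the T4 tables put MotB first, and T4 motB had a positive value in both, a small one (0.32 ± 0.10 at 5 min and 0.36 ± 0.10 at 10 min in the authors' deposited table, the latter not called at an adjusted p of 0.055), so it is weak support. The names of the host tables do not give the order; a positive value is read as higher with MotB in all 5 tables, and the direction of every host result rests on this reading. Gene names are those of the tables. The RefSeq gene table of assembly ASM584v2 (strain MG1655) was used for missing names, gene types and the order of neighbouring genes; 4408 of the 4414 host identifiers matched it and 6 did not. No coordinates are given, since the authors' build is not known.

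A gene was called at an adjusted p under 0.05, in either direction, with no minimum fold; "rose" and "fell" are used for such genes. Fixed before the data were examined were 21 gene lists (18 of the host, 3 of T4), the tests and the rule for the genes named: the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among host genes with a base mean of at least 10 (8 and 8 for T4), up to 4 members of a list with the smallest adjusted p, 5 genes for each difference between times, and always T4 motB, hns, stpA and E. coli motB. Other genes are said to have been chosen after their values were seen. The effect of MotB was compared between times by the difference of the log2 fold changes divided by the root of the summed squared standard errors, with Benjamini-Hochberg adjustment; the libraries of different times are different, although the fit shared their dispersions.

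Each list was tested against the other genes of its table with limma 3.58.1 (cameraPR on the Wald statistics, two-sided, preset inter-gene correlation of 0.01), in R 4.3.3. These 60 tests, 54 of the host and 6 of T4, were adjusted together. An inter-gene correlation cannot be estimated without values per library. Instead the list tests were repeated with a correlation of 0.05, and the host lists were rotated over the 4408 positions of the gene order, which keeps operons together; the smallest p that these rotations can give is 0.00023. Tests of lists for differences between times (57) and their rotations were added after the data were seen. Within each list the authors' p-values were also adjusted over the list alone. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

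The steps were tested on simulated data for 4414 genes with 200 genes changed. With the standard errors of the 5 min table, 42% of genes with a true log2 fold change of 1 were called, 90% at 2, 98% at 3 and 100% at 4, along with 0.285% of unchanged genes. For the difference between 5 and 0 min, 24%, 72%, 92% and 96% of genes with true differences of 1, 2, 3 and 4 were called. Errors were drawn with the standard errors that the test uses, and independently for the 2 times. In the data 163 genes had an unadjusted p under 0.05 for this difference, where 221 would by chance. The simulated errors thus differ from those of the data, and these shares may not hold there. Of the simulated lists without a shift, 2% had a p under 0.05. Where neighbours were correlated, rotation gave 2.5% for runs placed at random, against 21% for the same runs when neighbours were taken as independent. For runs that coincide with the correlated blocks rotation gave 9.5%, more than the nominal 5%, and the rate under independence was not computed.

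Alternatives were other thresholds for the adjusted p (0.01 and 0.1), a minimum log2 fold change of 1, a test against an absolute log2 fold change of at most 0.5, minimum base means of 10 and 50, and re-centring on the median gene or on the ribosomal protein genes. Left out after the data were seen were RNA genes, or genes deleted in TOP10 with those of a base mean under 1.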

Results

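Host and phage RNA was compared between E. coli cells with a plasmid that carries motB, the T4 gene for the protein MotB, and cells with the empty vector. The series' design text gives the aim as measuring what MotB does to host gene expression. MotB is the product of a T4 early gene. Cells were sampled 0, 5 and 10 min after infection with T4, with 2 libraries for each plasmid and time. There were 4414 host genes and 273 T4 genes. All fold changes compare MotB with vector at the same time and come, with their standard errors (SE), from the authors' deposited table of that time. Adjusted p-values are those of the authors' DESeq2 fit. Neither the names nor the headers of the host tables say which plasmid is the numerator, so the direction of every host result rests on the reading that positive means higher with MotB.

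At 0 min, cells with MotB had higher RNA of acid resistance and fimbrial genes and of genes that the nucleoid protein H-NS is known to silence. Envelope polysaccharide genes were higher as a list too, a call that was lost under rotation along the gene order (adjusted p = 0.056). Of 4414 genes, 582 were higher and 47 lower at 0 min. All acid fitness genes rose, along with appY, a regulator of anaerobic energy genes, and bglG, the antiterminator of the cryptic bgl operon. The decreases were few and small, with 3 of the 47 reaching a halving of RNA against 532 of the 582 increases reaching a doubling. The ribosomal protein genes, with 0 of 54 called, had a median log2 fold change of 0.05.

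All 14 acid fitness genes rose at 0 min (14 when adjusted over the list alone), with a median log2 fold change of 3.70. The activator gene of glutamate-dependent acid resistance, gadE, had a log2 fold change of 5.01 ± 0.41 (adjusted p = 9.6e-31) in the authors' deposited table. The regulators gadX and gadW stood at 3.62 ± 0.25 and 2.88 ± 0.24 in the authors' deposited table, and dctR at 4.35 ± 0.38. Of 40 listed H-NS-silenced genes, 30 rose and 0 fell (32 and 1 when adjusted over the list alone), with a median of 2.30. The authors' deposited table gives 5.26 ± 0.23 for appY (adjusted p = 2.9e-112), 4.48 ± 0.38 for hlyE, a pore-forming hemolysin, 4.96 ± 0.42 for bglG and 2.30 ± 0.25 for cadC, the activator of lysine decarboxylase. Among fimbrial and adhesin genes, 28 of 50 rose and 0 fell (30 and 0 when adjusted over the list alone), with a median of 1.67. The fimbrial genes yqiI and yqiH had 2.57 ± 0.27 and 3.51 ± 0.38 in the authors' deposited table, yadC 2.27 ± 0.25 and elfA 3.80 ± 0.49. Of 35 genes for the lipopolysaccharide (LPS) core and colanic acid, an exopolysaccharide, 17 rose and 1 fell (22 and 1 when adjusted over the list alone), with a median of 1.32. The colanic acid genes wcaD, wcaF and wcaE stood at 3.90 ± 0.59, 3.46 ± 0.60 and 5.66 ± 1.00 in the authors' deposited table, and waaZ of the LPS core at 1.78 ± 0.34.

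Genes of the nucleoid itself moved in part. H-NS RNA was higher, with hns at 1.25 ± 0.12 (adjusted p = 5.9e-22) in the authors' deposited table, as were its paralog stpA at 1.80 ± 0.26 and their partner gene hha at 2.84 ± 0.18. The last called member, cnu, had 0.48 ± 0.18 (adjusted p = 0.048) in the authors' deposited table, a call lost after re-centring on the ribosomal protein genes (adjusted p = 0.090). In all, 4 of 25 nucleoid and DNA topology genes rose and 0 fell (5 and 0 when adjusted over the list alone); the list's median of -0.18 and mean of 0.14 differ in sign. Cryptic prophage genes went both ways, with 26 of 156 higher and 6 lower (30 and 7 when adjusted over the list alone). The authors' deposited table has ybcK at 4.10 ± 0.54, sieB at 2.57 ± 0.36, cspI at 2.85 ± 0.41 and yfjI at 3.97 ± 0.58. Of 48 flagellar and chemotaxis genes 3 rose (3 when adjusted over the list alone): fliE at 6.55 ± 1.09, fliR at 3.44 ± 0.49 and fliQ at 1.90 ± 0.62 in the authors' deposited table, while the list's median was -0.11 and its mean 0.19. E. coli motB, a flagellar stator gene that shares only its symbol with the phage gene, had -0.26 ± 0.54 (adjusted p = 0.89) in the authors' deposited table.

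Other stress groups had few calls at 0 min. Among 24 RpoS-dependent genes the 3 that rose were hdeA (3.16 ± 0.40), gadA (4.75 ± 0.65) and osmB (1.65 ± 0.37) in the authors' deposited table, the first 2 being acid fitness genes as well. Of 24 SOS genes 2 rose, ruvA at 0.77 ± 0.19 and umuD at 2.82 ± 0.74 in the authors' deposited table. The cold shock list had 1 call of 16, the prophage gene cspI, and the maltose, galactitol and tryptophanase list had 1 of 23, gatD at 2.00 ± 0.54 in the authors' deposited table. These 4 lists had 3, 2, 1 and 1 calls when adjusted over the list alone. None of the 19 heat shock, 17 envelope stress, 33 respiration, 36 iron acquisition or 7 arabinose genes was called, over all genes or adjusted over the list alone. The iron acquisition genes had a median of -0.44 and were lower as a list (adjusted p = 0.028), a call lost with a correlation of 0.05 (adjusted p = 0.22) and under rotation (adjusted p = 0.13). The list test on ranks kept the call (adjusted p = 9.9e-04). Of the genes deleted in TOP10, 7 of 26 were listed and 1 was called, lacI at -0.32 ± 0.11 in the authors' deposited table (1 when adjusted over the list alone), which was lost after re-centring on the median gene (adjusted p = 0.25).

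Levels in each group were not analysed here, and for a gene near 0 in 1 group a fitted fold is no bound. Among the largest increases at 0 min, ybfQ had 8.06 ± 1.62 in the authors' deposited table, ykiC 7.05 ± 1.06, ypjC 6.86 ± 1.30, ygeF 6.61 ± 0.74 and fliE 6.55 ± 1.09. Next in the authors' deposited table came yibV (6.19 ± 0.75), ykfM (6.16 ± 0.73), fixB (6.10 ± 0.79) of a carnitine-related electron transfer operon, yhhZ (5.99 ± 0.68) and yrhD (5.86 ± 0.80). The largest decreases in the authors' deposited table were cueO, a copper oxidase, at -1.85 ± 0.59, marC at -1.11 ± 0.28, yddW at -1.02 ± 0.20, torI at -0.90 ± 0.26 and glsB at -0.87 ± 0.29. A further 5, yhfS (-0.97 ± 0.34), yoeF (-0.96 ± 0.35), tynA (-0.94 ± 0.33), mdtA (-0.93 ± 0.32) and ynjB (-0.92 ± 0.33), were called in the authors' deposited table and not after re-centring (adjusted p from 0.061 to 0.085). By the list test the acid fitness (adjusted p = 2.5e-40), H-NS-silenced (2.5e-28), fimbrial (1.0e-14) and LPS and colanic acid (2.1e-06) lists stood above the other genes. These held under a correlation of 0.05, and under rotation the first 3 had an adjusted p of 0.0014, the smallest seen, and the LPS and colanic acid list 0.056. The median gene lay at -0.10; re-centred on it, 631 genes were higher and 14 lower, with 596 calls shared, and re-centred on the ribosomal protein genes 562 were higher and 87 lower.

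**Figure D1:**
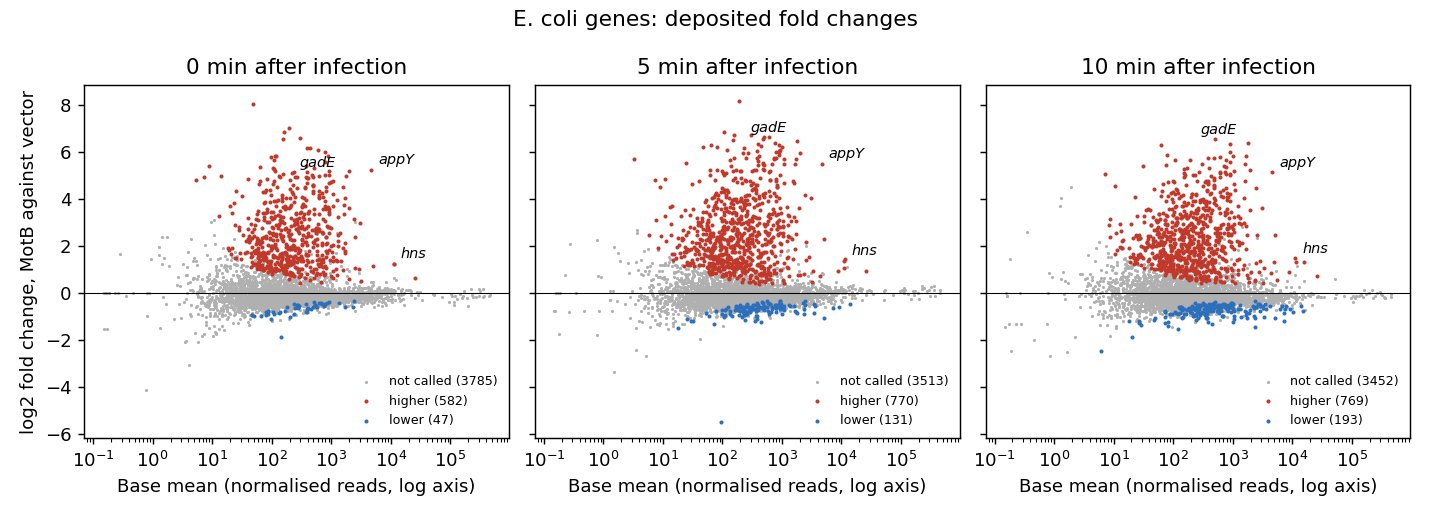
Log2 fold change of E. coli genes (MotB against vector) against their base mean in normalised reads (log axis) at 0, 5 and 10 min; each point is a gene, red higher and blue lower at an adjusted p under 0.05. Higher genes outnumber lower ones at each time, 582 against 47, 770 against 131 and 769 against 193.

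At 5 min after infection the same groups were higher with MotB, and more of their members were called. In all, 770 host genes were higher and 131 lower, and 687 of the increases were at least a doubling. Acid resistance genes, H-NS-silenced genes, fimbriae and the genes for LPS core and colanic acid again led, and the CRISPR-associated cascade gene casB was among the largest increases. Genes for ribosomal proteins (0 of 54 called, median 0.05) and arabinose use (0 of 7) were not called in either direction.

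All 14 acid fitness genes rose at 5 min (14 when adjusted over the list alone; median 4.75). The authors' deposited table gives gadE 6.47 ± 0.41 (adjusted p = 6.2e-53), gadX 3.63 ± 0.25, dctR 4.81 ± 0.33 and yhiD 4.81 ± 0.35. Of 40 H-NS-silenced genes, 34 rose and 0 fell (36 and 2 when adjusted over the list alone; median 3.20). Their leading members in the authors' deposited table were appY at 5.50 ± 0.22, hlyE 4.18 ± 0.31, cadC 2.51 ± 0.25 and gspC, of a cryptic type II secretion system, 3.80 ± 0.37. Of 50 fimbrial and adhesin genes, 39 rose and 1 fell (41 and 1 when adjusted over the list alone; median 2.11), with ecpB at 4.68 ± 0.40, yfcV at 4.89 ± 0.43, yqiI at 3.06 ± 0.27 and ygiL at 6.08 ± 0.57 in the authors' deposited table. Of 35 LPS core and colanic acid genes, 29 rose and 1 fell (31 and 1 when adjusted over the list alone; median 2.35). The authors' deposited table has the colanic acid genes wcaI at 4.41 ± 0.47, gmd at 3.96 ± 0.45 and wcaF at 4.20 ± 0.48, and waaZ at 3.04 ± 0.34.

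For nucleoid genes the count at 5 min was 5 higher and 1 lower of 25 (5 and 1 when adjusted over the list alone). Partner gene hha stood at 2.56 ± 0.17 in the authors' deposited table, hns at 1.38 ± 0.12 (adjusted p = 4.2e-27), stpA at 2.53 ± 0.26 and cbpA, a DnaJ-like DNA-binding protein, at 1.60 ± 0.20. The list's median was -0.11 and its mean 0.25. Cryptic prophage genes comprised 41 higher and 12 lower of 156 (43 and 14 when adjusted over the list alone), with ybcM at 3.36 ± 0.37, ybcK at 4.28 ± 0.51, yfjI at 4.05 ± 0.49 and cspI at 3.17 ± 0.39 in the authors' deposited table. Of 24 SOS genes 4 rose and 1 fell, in the authors' deposited table ruvA (1.50 ± 0.18), ruvB (1.21 ± 0.21), umuD (3.31 ± 0.68) and umuC higher and recA (-0.65 ± 0.17), the central recombinase, lower. The flagellar calls, 4 of 48, were fliE (6.53 ± 0.57), fliR (2.30 ± 0.42), fliQ (2.05 ± 0.55) and fliF (1.43 ± 0.39) in the authors' deposited table, with a list median of 0.07 and a mean of 0.30, while the test's sign was negative (adjusted p = 0.92).

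Among RpoS-dependent genes the called ones at 5 min were again hdeA (4.20 ± 0.39), gadA (6.22 ± 0.63) and osmB (1.98 ± 0.34) in the authors' deposited table, 3 of 24. The galactitol genes gatB (1.71 ± 0.50), gatD (1.80 ± 0.54) and gatC (1.54 ± 0.54) made up the 3 of 23 in the maltose, galactitol and tryptophanase list, per the authors' deposited table. Of 17 envelope stress genes 1 rose, the periplasmic chaperone gene spy at 1.54 ± 0.41 in the authors' deposited table, and of 33 respiration genes 2 did, cyoE (0.83 ± 0.30) and cyoC (0.78 ± 0.30); neither cyo gene was called when adjusted over the list alone, and cyoC was lost after re-centring on the ribosomal protein genes (adjusted p = 0.067). Cold shock genes had cspI higher and cspE (-0.64 ± 0.22) lower in the authors' deposited table. None of 19 heat shock and 36 iron acquisition genes was called, and 1 of 7 listed genes deleted in TOP10 was (lacI, -0.33 ± 0.11 in the authors' deposited table; adjusted p = 0.057 after re-centring on the median gene). Adjusted over the list alone, the SOS (4 higher, 1 lower), flagellar (4), RpoS-dependent (3), galactitol (3), envelope stress (1) and cold shock (1 higher, 1 lower) counts did not change.

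The largest increases at 5 min in the authors' deposited table were ykiC (8.18 ± 0.92), fixX (6.88 ± 1.08), ypjC (6.75 ± 0.91), ygeF (6.72 ± 0.55), gadB (6.66 ± 0.67), fixB (6.65 ± 0.73), casB (6.56 ± 0.70), fliE, gadE and yncI (6.40 ± 0.63). The largest decrease was yfaV at -5.49 ± 1.17, followed in the authors' deposited table by ypjF (-1.46 ± 0.48), yedF (-1.32 ± 0.39), the insertion sequence gene insG (-1.20 ± 0.20), rutG (-1.20 ± 0.43) and yjgX (-1.18 ± 0.32). The prophage genes yfjP (-1.16 ± 0.41), dicA (-1.14 ± 0.27) and yfjR (-1.11 ± 0.42; adjusted p = 0.059 after re-centring) and yjhU (-1.11 ± 0.27) completed the 10 in the authors' deposited table. By the list test the acid fitness (adjusted p = 3.3e-39), H-NS-silenced (2.6e-30), fimbrial (5.7e-19) and LPS and colanic acid (8.5e-16) lists stood above the other genes, the last with an adjusted p of 0.012 under rotation.

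At 10 min the same 4 lists were still higher with MotB, and heat shock genes were now called for the first time. In all, 769 genes were higher and 193 lower, and 669 increases were at least a doubling against 29 decreases of at least a halving. The glutamate decarboxylase genes gadB and gadA and their activator gadE were among the 10 largest increases. Of 19 heat shock genes 6 rose and 0 fell, where 0 had been called at 0 and at 5 min.

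All 14 acid fitness genes rose at 10 min (14 when adjusted over the list alone; median 4.96). The authors' deposited table gives gadE 6.39 ± 0.41 (adjusted p = 1.2e-50), dctR 5.14 ± 0.34, yhiD 5.17 ± 0.36 and gadX 3.54 ± 0.25. Of 40 H-NS-silenced genes, 35 rose and 0 fell (35 and 0 when adjusted over the list alone; median 3.19), with appY at 5.15 ± 0.23, hlyE at 3.54 ± 0.32 and the lysine decarboxylase operon genes cadA and cadB at 3.70 ± 0.36 and 4.08 ± 0.40 in the authors' deposited table. Fimbrial and adhesin genes counted 39 higher and 1 lower of 50 (42 and 1 when adjusted over the list alone; median 1.99). They included yqiI (2.96 ± 0.27), yfcV (4.23 ± 0.42) and ecpB (3.92 ± 0.40) in the authors' deposited table, and ygiL, 64.1-fold higher (log2 fold change with a 95% interval of 4.89 to 7.11). LPS core and colanic acid genes counted 29 higher and 1 lower of 35 (29 and 1 when adjusted over the list alone; median 2.71), led in the authors' deposited table by gmd (4.62 ± 0.48), fcl (4.23 ± 0.45), wcaI (4.27 ± 0.46) and wcaF (4.13 ± 0.49).

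The heat shock genes had a median of 0.73 at 10 min. Protease gene ftsH had 0.58 ± 0.13 in the authors' deposited table, hslO 0.79 ± 0.20, htpX 1.05 ± 0.34 and lon 0.88 ± 0.29, and the other 2 called members were dnaK and hslR. Adjusted over the list alone, 11 of 19 rose; the list test gave an adjusted p of 0.062, 0.22 with a correlation of 0.05, 0.13 under rotation and 0.00011 on ranks. Their difference from 5 min passed a list test chosen after the data were seen (adjusted p = 7.1e-19). Of 17 envelope stress genes 3 rose (2 when adjusted over the list alone), spy (1.59 ± 0.41), the protease gene degP (1.34 ± 0.38) and cpxP (0.91 ± 0.35) in the authors' deposited table. Nucleoid genes counted 4 higher and 3 lower of 25 (5 and 4 when adjusted over the list alone), with hha (2.53 ± 0.17), hns (1.48 ± 0.12; adjusted p = 6.6e-31), stpA (2.47 ± 0.26) and cbpA (1.93 ± 0.21) higher in the authors' deposited table. The lower ones were hupA and hupB, which encode the HU subunits, and ybaB; the list's median was -0.26 and its mean 0.17. Cryptic prophage genes counted 39 higher and 13 lower of 156 (42 and 15 when adjusted over the list alone), including ybcM (2.96 ± 0.37), cspI (2.94 ± 0.39), yfjJ (3.40 ± 0.49) and yfjI (3.38 ± 0.49) in the authors' deposited table.

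Of 24 SOS genes 4 rose and 2 fell at 10 min. These were ruvA (1.20 ± 0.19), ruvB (0.92 ± 0.21), umuC (1.31 ± 0.33) and umuD higher and dinI (-1.03 ± 0.26) and recA lower in the authors' deposited table. The 5 flagellar genes that rose, of 48, were fliE (5.11 ± 0.48), fliR (1.98 ± 0.42), fliF (1.49 ± 0.38), fliH (1.84 ± 0.64) and fliQ in the authors' deposited table; the list's median was -0.10 and its mean 0.23. RpoS-dependent calls were hdeA (4.49 ± 0.39), gadA (5.86 ± 0.64) and osmB (2.12 ± 0.35), and those of the galactitol list gatD (1.98 ± 0.54), gatB (1.66 ± 0.50) and gatC (1.46 ± 0.54), in the authors' deposited table. Cold shock genes had cspI higher and cspE at -0.82 ± 0.22 in the authors' deposited table, and lacI was at -0.34 ± 0.11 (adjusted p = 0.079 after re-centring on the median gene). None of 33 respiration, 36 iron acquisition, 7 arabinose or 54 ribosomal protein genes was called; the ribosomal median was -0.12, next to a median of -0.09 over genes with a base mean of at least 10. Adjusted over the list alone, 4 SOS genes were higher and 3 lower, and 5 flagellar, 3 RpoS-dependent and 2 galactitol genes were higher.

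The largest increases at 10 min in the authors' deposited table were gadB (6.55 ± 0.68), gadE, gadF (6.35 ± 0.47), yddL (6.32 ± 1.02), ygiL, yjbL (5.86 ± 0.98), gadA (5.86 ± 0.64), slp (5.85 ± 0.47), fixB (5.79 ± 0.72) and fixC (5.77 ± 0.69). The largest decreases in the authors' deposited table were xisD (-1.84 ± 0.57), yedE (-1.54 ± 0.44), the small RNA gene sokE (-1.43 ± 0.21), efeO (-1.40 ± 0.47) and yfjP (-1.33 ± 0.41). They were followed in the authors' deposited table by insG (-1.32 ± 0.20), yedF (-1.28 ± 0.38), yeeW (-1.26 ± 0.47; adjusted p = 0.060 after re-centring), yjhU (-1.24 ± 0.27) and yeeA (-1.22 ± 0.29). By the list test the acid fitness (adjusted p = 4.5e-44), H-NS-silenced (2.9e-31), LPS and colanic acid (3.3e-19; 0.0074 under rotation) and fimbrial (1.4e-18) lists stood above the other genes. Re-centring on the median gene gave 826 higher and 114 lower genes, and on the ribosomal protein genes 858 and 99. Reads of near-identical copies (gadA and gadB, insG) and of overlapping or antisense genes (gadY with gadX, arrS with gadE) could be assigned to either, so these values are uncertain.

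**Figure D2:**
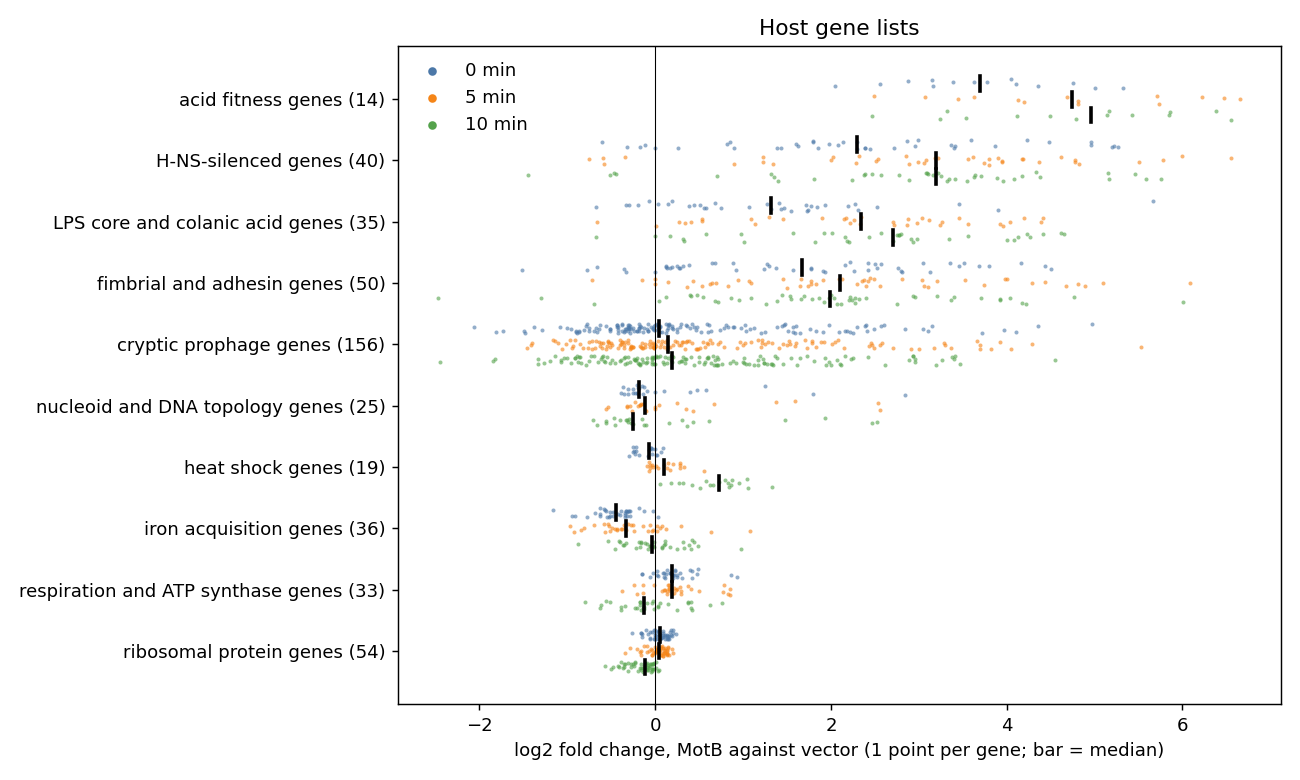
Log2 fold change (MotB against vector) of the members of 10 host gene lists at 0, 5 and 10 min; each point is a gene, the bar the median, and the number of genes stands in brackets. Acid fitness and H-NS-silenced genes lie to the right at each time, with medians of 3.70 and 2.30 at 0 min, while ribosomal protein genes lie near 0 and heat shock genes move to 0.73 at 10 min.

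Across the 3 times both higher and lower genes were shared more often than independent lists would be. Of 858 genes higher at any time, 545 were higher at each, where 17.7 would be shared by independent lists of those sizes. Of 252 lower at any time 18 were lower at each, where 0.061 would be shared by such lists. The 47 lower genes at 0 min cap that number, and 92 of the 131 lower at 5 min were also lower at 10 min. The times compare the same plasmids and share 1 fit, so the lists are not independent and the overlap is no replication. No gene was called in opposite directions. Over 4276 genes with a base mean of at least 10, which are not independent replicates, the fold changes correlated with r = 0.935 (rho = 0.767) between 0 and 5 min, 0.964 (rho = 0.839) between 5 and 10 min and 0.904 (rho = 0.712) between 0 and 10 min. Tested directly, the log2 fold change was more positive at 5 than at 0 min for 10 genes and at 10 than at 0 min for 13, and more negative for 0 in both tests. More positive was not always a larger effect, since yddW went from -1.02 ± 0.20 at 0 min to 0.16 ± 0.18 at 5 min in the authors' deposited table. Between 10 and 5 min 0 genes differed in the test of authors' fold changes, and 27 had an unadjusted p under 0.05, where 221 of 4414 would by chance. The other pairs had 163 (5 and 0 min) and 195 (10 and 0 min), so the test was conservative and the 0 is no sign that no gene differed.

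By values from the authors' deposited table, the difference between 5 and 0 min was 1.27 ± 0.25 for yahB, 1.18 ± 0.27 for yddW, 2.13 ± 0.51 for yhiM, 2.00 ± 0.48 for the efflux gene acrF and 1.57 ± 0.40 for fepE, an LPS O-antigen length regulator. After re-centring on the median gene, 1 of the 10, yahB, was still called, and the other 4 named had adjusted p-values from 0.056 to 0.069. Between 10 and 0 min it was, from the authors' deposited table, 3.88 ± 0.72 for wcaJ, which starts colanic acid synthesis, 1.64 ± 0.31 for the arsenite efflux gene arsB, 2.43 ± 0.49 and 1.89 ± 0.40 for appA and appC, genes of the appY regulon, and 1.17 ± 0.25 for yahB.

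In the phage, late genes were more abundant with MotB at 5 min. Of 48 listed late genes, most of which encode virion parts, 35 rose and 0 fell at 5 min (35 and 1 when adjusted over the list alone). Their median log2 fold change was 1.19, against -0.08 for 23 early and 0.12 for 22 middle genes. The largest increases were the baseplate genes 28 and 27 and the tail tube gene 19. Over all 273 T4 genes, 59 were higher and 6 lower, and 34 of the increases were at least a doubling.

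At 5 min gene 28 had a log2 fold change of 3.34 ± 0.36 in the authors' deposited table, gene 27 of 3.14 ± 0.24 (adjusted p = 4.7e-38), the tail tube gene 19 of 2.94 ± 0.40 and gene 29 of 2.60 ± 0.22. The tail assembly gene 51 was 5.67-fold higher there (log2 fold change with a 95% interval of 2.05 to 2.96). Next came segE (2.39 ± 0.31), a homing endonuclease gene, repEB (2.31 ± 0.54) and gene 17 (2.27 ± 0.24), the large terminase subunit, in the authors' deposited table; gene 8 (1.97 ± 0.17) is named as 1 of the 4 late genes with the smallest adjusted p. Of the middle genes 5 rose (5 when adjusted over the list alone), among them in the authors' deposited table gene 1 (0.51 ± 0.08), gene 46 (0.43 ± 0.10), regA (0.32 ± 0.11) and uvsY (0.33 ± 0.12). Of the early genes 2 rose and 2 fell (2 and 1 when adjusted over the list alone), in the authors' deposited table motB (0.32 ± 0.10; adjusted p = 0.0089) and mrh (0.42 ± 0.15) higher and the topoisomerase genes 52 (-0.37 ± 0.09) and 39 (-0.23 ± 0.09) lower. The other decreases in the authors' deposited table were motA.1 (-0.46 ± 0.13), vs.7 (-0.37 ± 0.10), nrdA.1 (-0.30 ± 0.09) and b-gt (-0.21 ± 0.08). Re-centring on the median T4 gene ended the calls of gene 39 (adjusted p = 0.12) and b-gt (adjusted p = 0.13). By the list test the late genes stood above the others (adjusted p = 3.3e-24), while the early (adjusted p = 0.072) and middle lists (0.94) did not differ past the threshold. T4 motB is encoded by the phage in both arms and by the plasmid in 1, and its base mean of 66075 was 21.5% of the T4 total. Its log2 fold change was small at 5 and 10 min (0.32 and 0.36), and no T4 comparison was at hand at 0 min. Expression of motB from the plasmid before infection was therefore not seen here.

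At 10 min a single T4 gene passed the test between the arms. This was segD, a homing endonuclease gene, at 0.67 ± 0.16 (adjusted p = 0.0047) in the authors' deposited table. T4 motB had 0.36 ± 0.10 (adjusted p = 0.055) in the authors' deposited table. At an unadjusted p under 0.05 there were 10 genes in the authors' DESeq2 table, where 13.65 of 273 would be by chance. None of the 48 late, 22 middle and 23 early genes was called, and adjusted over the list alone 1 early gene was, motB. The late genes had a median of 0.03, with in the authors' deposited table gene 11 at 0.18 ± 0.12, gene 8 at 0.23 ± 0.17, gene 29 at 0.26 ± 0.19 and gene 48 at 0.28 ± 0.22. The early and middle medians were 0.05 and -0.003, and no list differed from the other T4 genes (adjusted p from 0.53 to 0.80).

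**Figure D3:**
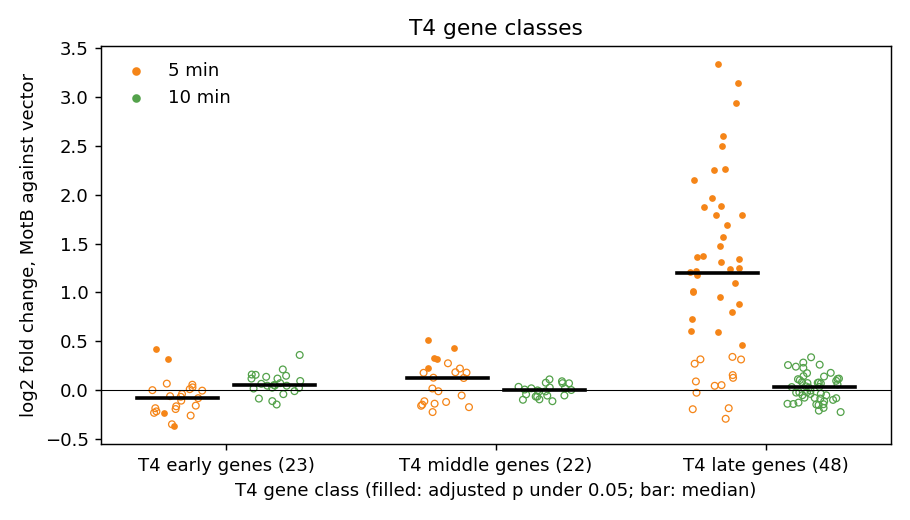
Log2 fold change (MotB against vector) of T4 early, middle and late genes at 5 and 10 min; each point is a gene, filled where the adjusted p is under 0.05, and the bar is the median. Late genes have a median of 1.19 at 5 min and 0.03 at 10 min.

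The loss of the late-gene difference between 5 and 10 min passed its own test. The MotB effect was smaller at 10 than at 5 min for 40 of 273 T4 genes and larger for 0, and 31 of the 40 were late genes, 1 was a middle gene and 8 were in no list. By values from the authors' deposited table, the difference was -3.04 ± 0.31 for gene 27, -2.56 ± 0.30 for gene 51, -2.34 ± 0.29 for gene 29, -1.94 ± 0.26 for the tail fiber socket gene 9 and -1.74 ± 0.24 for gene 8.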

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

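All results here were picked because the MotB effect differed between time points in a test of the difference; the tests of explanations and the list tests of time differences were chosen after the results were seen.

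Host log2 fold changes were more positive at 5 and 10 min than at 0 min for several lists and for few single genes. Cultures sampled later had also had more time since arabinose was added, and no group was left uninfected at 5 or 10 min. Infection and longer induction therefore cannot be told apart. Single genes that differed numbered 10 between 5 and 0 min and 13 between 10 and 0 min, all of them more positive at the later time; for yddW this was the loss of a decrease, from -1.02 ± 0.20 to 0.16 ± 0.18 in the authors' deposited table. After re-centring on the median gene, 1 of the 10, yahB, was still called. The median gene lay at -0.054 at 5 min and -0.102 at 0 min, so re-centring moved the differences themselves little. The other named genes had adjusted p-values from 0.025 to 0.043 in the test before it, so their calls sat close to the threshold. By values from the authors' deposited table, the differences were 1.27 (yahB), 1.18 (yddW), 2.13 (yhiM), 2.00 (acrF) and 1.57 (fepE) between 5 and 0 min, and 3.88 (wcaJ), 1.64 (arsB), 2.43 (appA), 1.89 (appC) and 1.17 (yahB) between 10 and 0 min. Between 5 and 0 min the lists with more positive fold changes were the LPS core and colanic acid genes (adjusted p = 1.4e-18, median difference 1.15), acid fitness genes (2.1e-07, 0.97), H-NS-silenced genes (2.1e-07, 0.75) and fimbrial and adhesin genes (9.0e-07, 0.49). Between 10 and 0 min the same lists had adjusted p-values of 8.8e-20, 1.2e-07, 5.5e-05 and 9.4e-04. Under rotation along the gene order these stayed under 0.05, with a largest adjusted p of 0.023.

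These are differences between the MotB-against-vector fold changes of 2 times, not changes of RNA over time. As a list, heat shock genes had more positive fold changes at 10 min than at 0 min (adjusted p = 8.6e-14, median difference 0.81) and than at 5 min (7.1e-19, 0.59), both with an adjusted p of 0.0031 under rotation, although the list test at 10 min itself did not pass (adjusted p = 0.062). Iron acquisition genes had median differences of 0.43 at 10 against 0 min (adjusted p = 0.023; 0.098 under rotation) and 0.27 at 10 against 5 min (4.3e-04; 0.0031 under rotation). Respiration and ATP synthase genes had more negative fold changes at 10 min, with median differences of -0.30 against 0 min (adjusted p = 5.5e-05; 0.031 under rotation) and -0.31 against 5 min (3.2e-06; 0.0031 under rotation); 0 of 33 were called at 10 min, and the list test there did not pass (adjusted p = 0.41). Ribosomal protein genes had -0.22 at 10 against 0 min (adjusted p = 0.019; 0.0996 under rotation).

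In T4, 40 genes had a smaller MotB effect at 10 than at 5 min. The authors' deposited table gives differences of -3.04 (gene 27), -2.56 (gene 51), -2.34 (gene 29), -1.94 (gene 9) and -1.74 (gene 8). The late list carried this change (adjusted p = 3.5e-26). The list test of the early genes had the other sign (adjusted p = 0.023), but its background holds the late genes and 0 of 23 early genes differed. A shift of the early genes themselves is therefore not shown.

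The late-gene increase at 5 min was weighed against 3 explanations. A single scaling factor between the libraries would move all T4 genes alike. Late genes lay 1.27 above the other T4 genes in median log2 fold change (95% bootstrap interval over genes 0.88 to 1.43). Such a factor cannot open this gap, but the gap restates the list difference already seen and is no independent test. Noise of low counts would scatter late genes around 0. Of the late genes 91.7% (44 of 48, exact 95% interval 80.0 to 97.7, with genes taken as independent) were above 0. As 35 of the 48 had already been called higher and 0 lower, this share restates the finding and is no independent test. Whether MotB cultures were further along the infection when sampled cannot be told apart from a change in the phage programme. The list test of the early genes at 5 min did not pass (adjusted p = 0.0716). Its background holds the raised late genes, so its negative sign carries no information on timing. The early median was -0.08, next to -0.07 for all T4 genes outside the late list. Late genes were level at 10 min (median 0.03), and the change between times within an arm was not analysed here. The cause was left open.

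The increase of H-NS-silenced genes was weighed as well. A scaling factor would shift all genes alike, but the list lay 2.25 above the ribosomal protein genes in median at 0 min (95% bootstrap interval 1.75 to 2.87). This gap too restates a list difference already seen and is no independent test. Of the list's members with a base mean of at least 50, 78.4% (29 of 37, exact 95% interval 61.8 to 90.2, with genes taken as independent) were called at 0 min. This largely restates the calls, as 30 of the 40 listed members rose. The base mean is averaged over libraries, so a gene near 0 with vector can pass through its MotB reads. Low counts with vector are therefore not excluded. Calls carried by correlated neighbours are argued against by the rotation test (adjusted p = 0.00136), which can be too small where lists follow operons. Each arm is 1 plasmid-bearing strain, so any other difference between the 2 strains stays open, untested; loosened silencing of H-NS targets by MotB is a hypothesis for which no independent test is at hand.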

How the results depend on the processing

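The alternatives of RNA genes left out, and of genes deleted in TOP10 left out, were chosen after seeing the data. No paired analysis was possible because the tables give no values per library; leaving out a replicate, the replicate block and a second count model were not run for that reason. Tested against an absolute log2 fold change of at most 0.5, the host counts fell to 414, 591 and 544 at 0, 5 and 10 min and the T4 counts to 30 at 5 min and 0 at 10 min; this null is stricter by construction. A minimum log2 fold change of 1 left 34 T4 genes at 5 min and 0 at 10 min, and a threshold of 0.1 gave 2 at 10 min. Re-centring on the median left 1 gene between 5 and 0 min; the 4 named genes lost had adjusted p-values from 0.025 to 0.043 before and from 0.056 to 0.069 after, so the calls sat close to the threshold. Other total counts stayed within 1.5 times, from 503 to 730 at 0 min. Counts of lower host genes moved more: over the thresholds and re-centrings, 47 at 0 min became 12 to 99, 131 at 5 min became 60 to 202 and 193 at 10 min became 98 to 289. The ribosomal protein list, not called at 0 min, turned from lower to higher on ranks (adjusted p = 0.0298). Its median log2 fold change of 0.05 lay above the -0.10 of the median gene. The main test compares means, and its background for this list holds all 582 higher genes. The cause was not tested further. Called list and table pairs numbered 13 among host lists, 11 under rotation and 19 on ranks, where those added were the respiration list at 0 min (adjusted p = 2.5e-04) and 5 min (0.023), the maltose, galactitol and tryptophanase list at both (0.023), the ribosomal protein list at 0 min and the heat shock list at 10 min. No named gene reversed. Re-centring on the median ended 12 calls of named genes and on ribosomal protein genes 4. Stricter settings ended more: 31 at an adjusted p threshold of 0.01, 35 with a minimum log2 fold change of 1 and 63 when tested against 0.5. Depth per library is unknown, so precision rests on the standard errors.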

Other observations

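The summaries of neighbouring genes and RNA classes and the test of strain here were chosen after the data were seen, as were the genes named in them.

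Genes that were higher at all 3 times lay side by side on the chromosome. Of the 543 such genes with a place in the gene order, 182 (33.5%) fell in 25 runs of at least 5 neighbours that were all higher at each time. Genes of an operon are transcribed together, so neighbours are not independent and the runs were not tested. The longest run, of 15 genes from slp to gadA, holds the acid fitness island and had median log2 fold changes of 3.77, 4.69 and 4.79 at 0, 5 and 10 min. The next, of 14 genes from yqeH to ygeO, is a remnant of a type III secretion system, with medians of 4.66, 5.71 and 4.39. Others were waaL to waaP of the LPS core (9 genes; 1.72, 2.87 and 2.71), emrK to yfdX with the 2-component genes evgA and evgS (8 genes; 2.87, 3.19 and 2.88), gspB to gspH of type II secretion (8 genes; 2.58, 3.12 and 3.02), and cas2 to casA of the CRISPR system (7 genes; 2.39, 4.78 and 4.38). The runs nudI to arnT, for lipid A modification (7 genes), and csgG to csgB, for curli (5 genes), had medians of 2.21 and 4.23 at 0 min. The run bcsA to bcsG, for cellulose synthesis, had the lowest at 0 min, 0.96.

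Of 107 pseudogenes 44 were higher and 0 lower at 0 min, and of 4133 protein-coding genes 528 and 45; this difference was not tested. Among 68 small RNA genes 7 were higher and 2 lower at 0 min, and 8 and 12 at 10 min. Higher at 10 min in the authors' deposited table were gadF (6.35 ± 0.47), arrS (5.20 ± 0.48), rseX (4.93 ± 0.66), gadY (2.46 ± 0.22), ralA (2.03 ± 0.52), ryfA (1.00 ± 0.23), glmZ (0.74 ± 0.18) and csrC (0.90 ± 0.35; adjusted p = 0.048). The small RNA csrB, which like csrC sequesters the regulator CsrA but moved the other way, was at -0.76 ± 0.16 and mcaS at -1.04 ± 0.21 in the authors' deposited table at that time. The toxin gene rnlA, for an mRNA endonuclease known from T4 infection, and its antitoxin gene rnlB were lower at each time: the authors' deposited table gives -0.79 ± 0.22, -0.97 ± 0.22 and -1.04 ± 0.22 for rnlA and -0.63, -0.91 and -0.91 for rnlB at 0, 5 and 10 min. Within the H-NS-silenced list, bglF, bglB, proW and proX were not called at 10 min, with -0.51, 0.70, -0.47 and -0.45 in the authors' deposited table, although bglG of the same operon was called at 0 min; leuO, not called either, had a base mean of 0.150 and carries no information.

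In T4, a few genes with high base means had wide errors at 5 min in the authors' deposited table: gene 30 (base mean 27197; -0.23 ± 1.39), vs.6 (17745; -0.23 ± 0.76) and nrdA (6972; -0.14 ± 0.85).

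The strain named in the labels was tested with the host tables. If the cultures were of a TOP10-type strain, genes deleted in it should be near 0, and 0% of the 20 such genes reached a base mean of 10, with the lac genes and araC left out because a plasmid can carry them. Of these 20 genes 2 were listed, at base means up to 0.267, while 93.7% of 4270 other protein-coding genes reached 10. The 20 genes form 6 groups of neighbours and are not independent. In a permutation test that rotated them together over all 4290 positions of the protein-coding gene order, only the real position had as few genes at 10 (p = 2.3e-04). This is consistent with cultures of a TOP10-type strain, as a hypothesis, and it rests mostly on genes that are not listed among those analysed here. Runs of at least 10 protein-coding genes with no listed gene over a base mean of 2 were yabI to ilvH (16 genes), ymfD to mcrA of the e14 prophage (21) and fimB to lgoD (48).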
